A study of Mus musculus with 4 samples.

How the data were processed

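The study profiled the DNA bound by XBP1s, the spliced and transcriptionally active form of the unfolded protein response factor XBP1, in natural killer (NK) cells purified from mouse spleen. Per the labels' protocols, the cells were treated with the cytokine IL-15 at 50 ng/ml for 1 h, fixed in 1% formaldehyde for 10 min, and sonicated. Chromatin was then precipitated with an antibody against XBP1s, and 2% of the chromatin was kept as input. Libraries were sequenced as paired-end reads of 100 bp. The 4 libraries fall into 2 groups by their titles, 2 XBP1s immunoprecipitations and 2 inputs. The protocol also names a T-bet antibody and an IgG control; data from these were not analysed here.

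One table of peaks was analysed. Per the file header, it is the output of the HOMER peak annotator run on 1 set of intervals, which the header's name for the input calls common, with genome build mm10, and it holds no column of any single library. The submitters' processing notes name Trim Galore 0.6.7, FastQC 0.11.9, Bowtie2 2.4.5, MACS2 2.2.7.1 and HOMER 4.11.1 and 4.11, with builds GRCm38 and mm10. Which peak calls were combined, with what threshold, and whether libraries were pooled before calling is not given in the sources used here. The score column that the authors deposited is 0 for all 4890 peaks, so it carries no peak strength. The intervals do not overlap each other and range from 1 to 3413 bp. Of these, 109 (2.23%) are shorter than 100 bp and 465 shorter than 200 bp. The width of an interval, end minus start plus 1, was therefore the only quantity per peak, and it replaced the peak strength that had been planned for ranking. Width is not a measure of signal. Where intervals are the shared parts of several calls, a width is that of the overlap and not of a whole peak, and the sources used here do not settle this.

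Positions are given as in the deposited table, 1-based on mm10. Distances to the nearest transcription start site (TSS), the nearest gene and the annotation class (promoter, exon, intron and so on) are the authors' own, from HOMER. Genes were matched by Entrez number to a RefSeq gene table of GRCm38.p6, the assembly of mm10. The nearest gene of 4885 of the 4890 peaks (99.9%) was found there. For 1998 of 3806 peaks within 5000 bp of the TSS of a protein-coding gene (52.5%), the TSS implied by the authors' distance lay within 10 bp of an end of that gene in the table; alternative start sites were not looked up. That table gives no strand.

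A gene counted as having a peak when it was the authors' nearest gene of a peak whose centre lay within 5000 bp of its TSS. For each of 18 gene lists (536 entries, all matched, 5 of them through an older symbol), the share of members with a peak was compared with that of the other protein-coding genes among 21900, using a two-sided exact Fisher test with Benjamini-Hochberg adjustment over the 18 lists. Lists were compared with each other directly by the same test, adjusted over 6 comparisons. Widths were compared as differences of medians of the widest peak per gene, with two-sided permutation tests of 100000 resamples, adjusted over the 12 lists with at least 3 such genes. The smallest p these permutations can give is 1e-05. Intervals on shares are exact Clopper-Pearson 95% intervals; they cover counting error only. Peak positions were compared with 97760 random positions on the same chromosomes, 20 per peak. Peaks per chromosome were compared with the span from the first to the last RefSeq gene by exact binomial tests. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

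The groups, the gene lists and their test against other genes, the annotation shares, the comparison of promoter and distal peaks, the distribution over chromosomes and the rule for named genes were fixed before the data were examined. Other tests were chosen after the list shares had been seen: the direct comparisons between lists, the widths per list, the measure of gene ends, the expectation by gene number, the test of unassigned genes and the comparisons of distal peaks and gene families. The fixed rule ranked genes by peak strength, for which width was used. It names Xbp1 and Pim2, 10 other genes of interest, the genes of the 12 widest peaks within 5000 bp of a TSS, the 5 widest peaks farther away, and in each list up to 5 members with the widest peaks. Some genes that this rule takes in are not reported here. The list test was tested on simulated data of 21900 genes. It called 92.5% of lists planted at a share of 50%, 100% of those planted at 80%, and 0.571% of lists with no planted difference. Alternatives varied the distance window, the peaks used, the assignment of genes and the background. Some planned steps were not run. The 14 sequence motifs were not searched because no genome sequence was used here, and the CpG-rich promoter background was left out for the same reason. Agreement between replicates, tests without each replicate and depth per library could not be had from a combined list.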

Results

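XBP1s occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse splenic NK cells, lymphocytes that kill infected and tumour cells, after 1 h with IL-15, a cytokine that maintains them. The series holds 2 XBP1s immunoprecipitations and 2 inputs, and the values analysed are 1 combined list of 4890 peaks. The peaks cover 2292 kb and have a median width of 373 bp (interquartile range 258 to 578). Because the list has no values per library, there is no replicate error for any peak or width, the depth of each library is unknown, and no difference between libraries was tested. Whether an interval is a whole peak or the shared part of several calls is not given in the sources used here, so widths are those of the listed intervals. All tests below compare genes or peaks within the list, and neither are independent replicates.

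The first question was where XBP1s peaks lie. They were concentrated at the start of genes: 74.4% lay within 1000 bp of a TSS (95% interval 73.2 to 75.6). The median peak centre was 53 bp downstream of the TSS (interquartile range -142 to 249 bp). HOMER placed 2571 peaks (52.6%) in promoters, 1037 (21.2%) in introns, 608 (12.4%) between genes, 267 (5.46%) in 5' untranslated regions and 255 (5.21%) in exons. Within 1000 bp of either end of a protein-coding gene lay 65.6% of peak centres (95% interval 64.3 to 67.0), against 3.30% of random positions on the same chromosomes, a ratio of 19.9. This ratio depends on the window and was 8.48 with a window of 3000 bp. A further 885 peaks (18.1%) lay more than 5000 bp from a TSS.

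**Figure D1:**
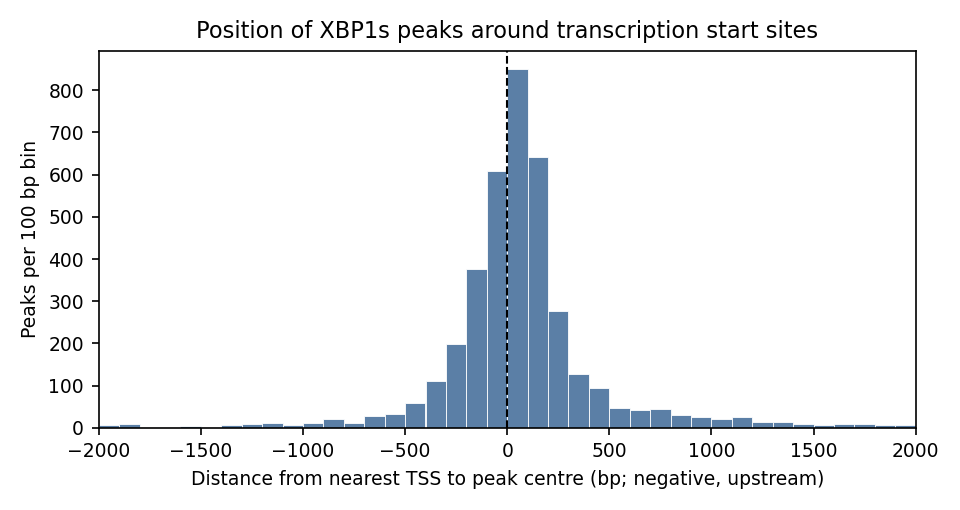
Number of peaks (vertical axis, per bin of 100 bp) by the distance from the nearest transcription start site to the peak centre (horizontal axis, bp, negative upstream), for the range within 2000 bp of a start site. Peaks gather around the start site, with a median distance of 53 bp over all 4890 peaks.

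The second question was which genes carry XBP1s peaks, beginning with the endoplasmic reticulum (ER) and secretory genes that XBP1s is known to control. Nearly all of them did. Of 37 genes of ER protein import and glycosylation, 34 had a peak within 5000 bp of the TSS (91.9%, 95% interval 78.1 to 98.3), as did 27 of 30 ER chaperone and folding genes (90%, 73.5 to 97.9), 35 of 41 genes of ER to Golgi transport (85.4%, 70.8 to 94.4) and 17 of 23 genes of ER-associated degradation (73.9%, 51.6 to 89.8). Over all 21900 protein-coding genes the share was 15.9% (3487 genes). By the exact Fisher test, each of these 4 lists exceeded the other genes, with adjusted p of 5.47e-23, 3.88e-18, 1.52e-21 and 3.61e-09 in the order given.

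The widest peaks of each list were as follows. Among the import genes were Sec11c, a catalytic subunit of signal peptidase (2705 bp), Sec61g, a subunit of the translocon channel (2273 bp), Stt3a, a catalytic subunit of oligosaccharyltransferase (2227 bp), the glycosyltransferase gene Alg2 (1988 bp) and Spcs3 of signal peptidase (1899 bp). Among the chaperones were Canx, which encodes calnexin (2785 bp; chromosome 11, 50324050 to 50326834, annotated to intron 1), Hspa5, which encodes the chaperone BiP (2365 bp; chromosome 2, 34770863 to 34773227, promoter), the disulfide isomerase genes Pdia4 (2348 bp) and Pdia3 (2097 bp), and Txndc11 (2292 bp). Genes of degradation had Herpud1 (1773 bp), Ube2g2 (1559 bp), Edem1 (1470 bp; chromosome 6, 108827807 to 108829276, centred 100 bp upstream of the TSS), the ubiquitin ligase gene Syvn1 (1378 bp) and Selenos (1317 bp). Transport genes had Sec24c (2011 bp) and Sec24d (1540 bp) of the COPII coat, Surf4 (1503 bp), Tmed10 (1442 bp) and Lman2 (1432 bp). Dnajb9, an ER co-chaperone, had a peak of 1359 bp and Sec61a1, the translocon's channel-forming subunit, one of 1395 bp.

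**Figure D2:**
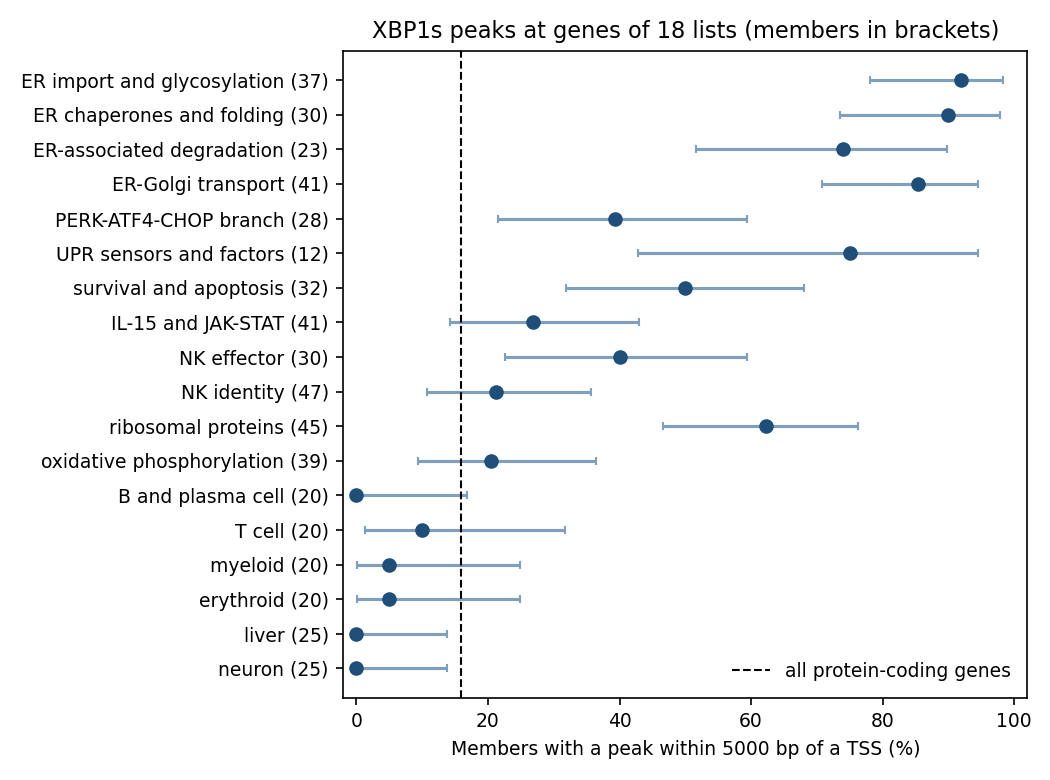
Share of members of each of 18 gene lists with a peak within 5000 bp of a transcription start site (horizontal axis, percent), with exact 95% binomial intervals; the number of members is in brackets and the dashed line is the share over all protein-coding genes, 15.9%. The ER and secretory lists lie between 73.9% and 91.9%, and the B cell, liver and neuron lists at 0.

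Peaks at these genes were also wide. The widest peak per gene had a median of 1132 bp over the 113 ER and secretory genes with a peak (interquartile range 717 to 1448), against 404 bp over the other 3374 genes, a difference of 728 bp (permutation p = 1e-05, the smallest possible). Medians were 1290.5 bp for import, 1274 bp for chaperones, 870 bp for transport and 717 bp for degradation (permutation, adjusted p = 4.00e-05 for the first 3 and 0.00396 for degradation). Without the widest 1% of peaks, the excess of import over other genes fell from 882.5 to 574 bp (permutation adjusted p = 4.00e-05). Of the 100 genes with the widest peaks 34 were on these lists, and of the widest 10% of genes 69 of 349 (19.8%, 95% interval 15.7 to 24.3), while the narrowest 10% held none (0 of 349, interval up to 1.05%).

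**Figure D3:**
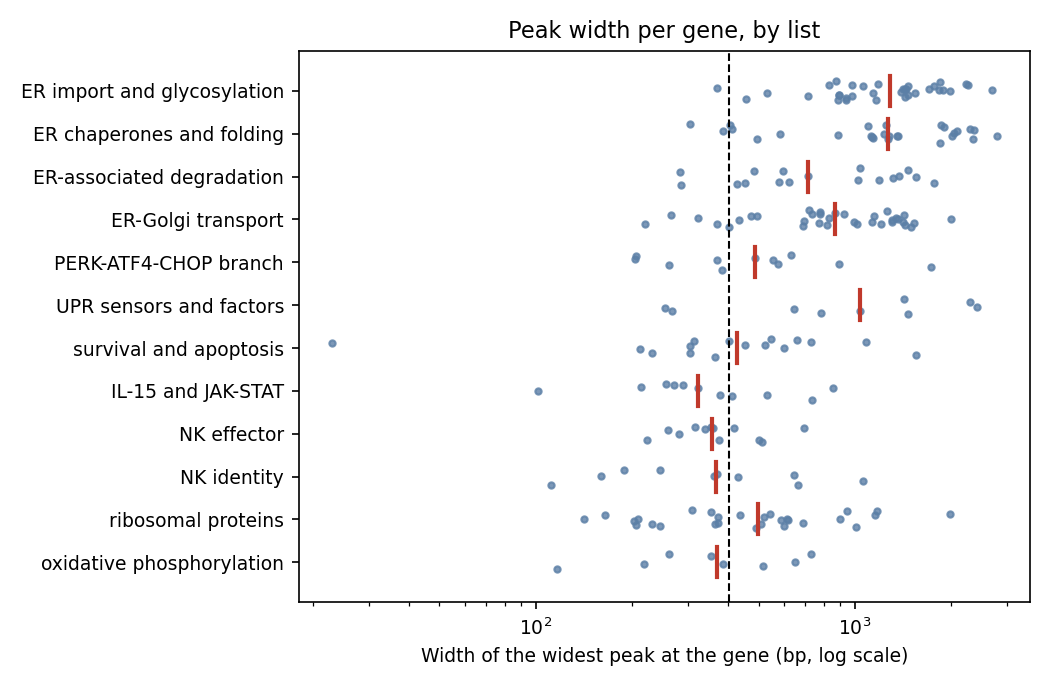
Width of the widest peak within 5000 bp of the start site of each gene (horizontal axis, bp, log scale), 1 point per gene, for the 12 lists with at least 3 such genes. Red bars are list medians and the dashed line is the median of genes outside the ER and secretory lists, 404 bp; the medians of import and chaperone genes are 1290.5 and 1274 bp.

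The 4 lists held 18 members with no assigned peak. For 11 of these (61.1%, 95% interval 35.7 to 82.7) a peak assigned to another gene lay within 1000 bp of a gene end, compared with 4.26% of 18395 other unassigned protein-coding genes (exact Fisher p = 2.16e-11). They include Hsp90b1, which encodes the ER chaperone GRP94, whose end lies inside the 2446 bp peak assigned to Ttc41. Serp1 ends inside the 2751 bp peak assigned to Eif2a, and Sec61b inside the 1988 bp peak of Alg2. These 3 genes were singled out after their values were seen. In all, 124 of 131 members had an assigned peak or such a peak of another gene.

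The unfolded protein response has further branches. Of 12 of its sensors and factors, 9 had a peak (75%, 95% interval 42.8 to 94.5; exact Fisher adjusted p = 2.32e-05), with a median width of 1037 bp (permutation adjusted p = 8.10e-04). The 5 widest were at Creb3l2 (2414 bp), Xbp1 (2296 bp), Atf6 (1469 bp), Eif2ak3, which encodes the kinase PERK (1430 bp), and Nfe2l1 (1037 bp). The median width of this list exceeded that of other genes by 627 bp. Without the widest 1% of peaks it did so by 377 bp (permutation adjusted p = 0.0214). In the branch downstream of PERK, of amino acid synthesis and transport and ATF4 and CHOP targets, 11 of 28 genes had a peak (39.3%, 21.5 to 59.4; exact Fisher adjusted p = 0.00502). Atf4 had the widest (1733 bp), followed by the arginine transporter gene Slc7a1 (892 bp), Psat1 (631 bp), Nars (574 bp) and Slc3a2 (554 bp). The share in this branch was lower than in the ER and secretory lists together (113 of 131, 86.3%; exact Fisher adjusted p = 1.49e-06), and its widths did not differ detectably from other genes (median 487 bp, permutation adjusted p = 0.607). Among the widest 10% of peaks alone, its excess did not pass (7.14% against 1.92% of other genes, exact Fisher adjusted p = 0.259).

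The series is about a relation between XBP1s and the survival kinase PIM-2, so both genes were examined. Pim2 had 1 peak of 231 bp (chromosome X, 7878322 to 7878552), centred 131 bp downstream of the TSS in exon 1 of 6. The width is below the lower quartile of all peaks (258 bp). Xbp1 had 2 peaks: 1 of 2296 bp over exon 1 of 6 (chromosome 11, 5519907 to 5522202, centred 413 bp downstream of the TSS), among the 12 widest within 5000 bp of a TSS, and 1 of 490 bp (5505926 to 5506415) 14471 bp upstream, annotated as intergenic, where the RefSeq table places an end of the noncoding gene Gm11963.

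**Figure D4:**
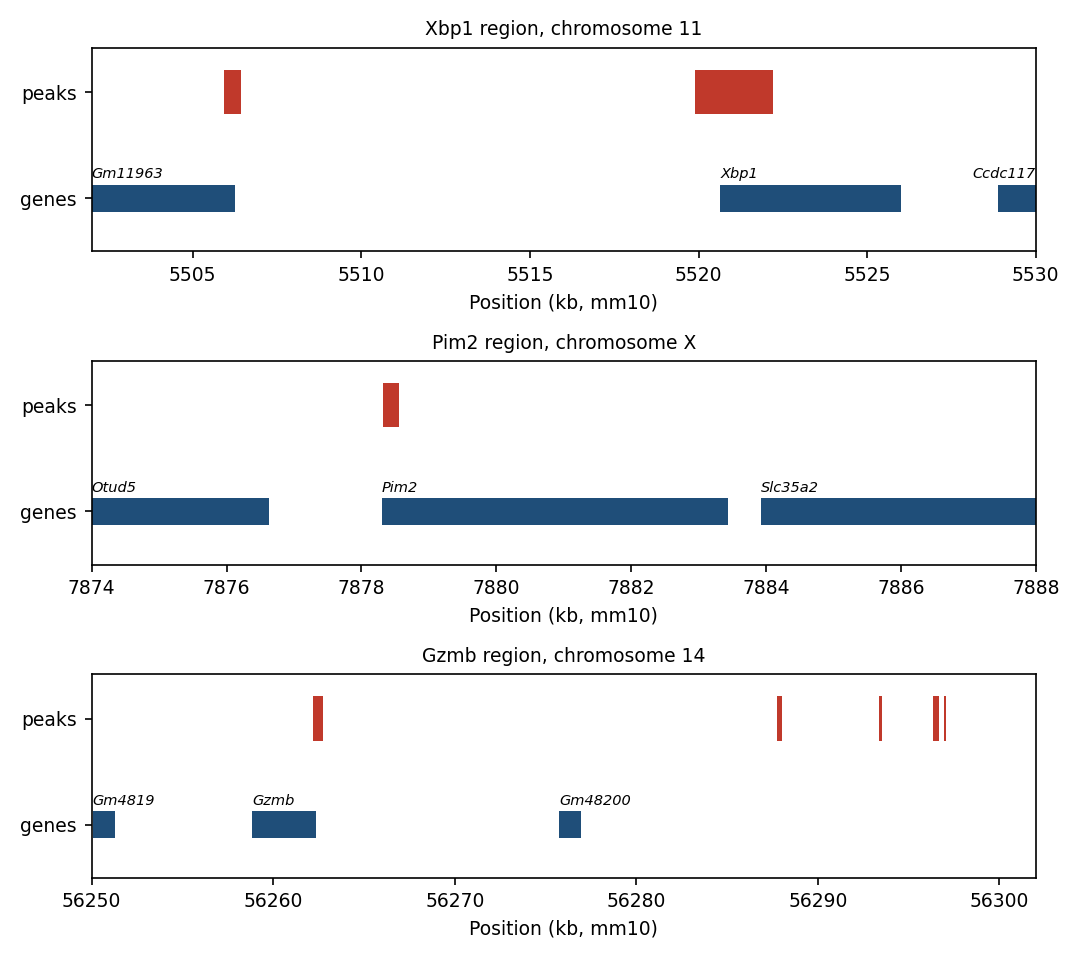
Peaks (red) and RefSeq genes (blue) to scale around Xbp1, Pim2 and Gzmb (horizontal axis, position in kb on mm10). The 2296 bp peak lies over the start of Xbp1, the 231 bp peak just inside the start of Pim2, and 4 of the 5 peaks assigned to Gzmb lie 25572 bp or more upstream of it.

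Among 32 survival and apoptosis genes, 16 had a peak (50%, 95% interval 31.9 to 68.1; exact Fisher adjusted p = 2.28e-05), with a median width of 429.5 bp that did not differ detectably from other genes (permutation adjusted p = 0.792). The list holds genes that protect cells and genes that promote death. The widest peaks were at Birc2, an inhibitor of apoptosis (1563 bp), the kinase gene Pim3 (1082 bp), Cycs, which encodes cytochrome c (731 bp), Cflar (660 bp) and Birc5 (602 bp). The anti-apoptotic gene Bcl2 had a peak of 366 bp in the 5' untranslated region (chromosome 1, 106713986 to 106714351). Mcl1, another anti-apoptotic gene, had 3 peaks, of 405 bp at the promoter, 307 bp in intron 1 of 2 and 248 bp at 10235 bp downstream. Among the widest 10% of peaks alone the excess did not pass (6.25% against 1.92% of other genes, exact Fisher adjusted p = 0.284). The excess is over all other protein-coding genes. The share was 62.2% for ribosomal protein genes, 43.8% for proteasome genes and 20.5% for oxidative phosphorylation genes. Survival genes were not tested against any of these, so a preference for them over other expressed genes was not shown.

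NK cell genes had peaks less often than the ER and secretory genes (exact Fisher adjusted p = 2.16e-16). Of 30 effector genes 12 had one (40%, 95% interval 22.7 to 59.4; exact Fisher adjusted p = 0.00302), and of 47 identity genes 10 (21.3%, 10.7 to 35.7; adjusted p = 0.396). With peaks at any distance counted, the identity share was 34.0% against 17.7% of other genes and passed (exact Fisher adjusted p = 0.0119). It passed in no other setting. Within 1000 bp the identity share lay below that of other genes (10.6% against 15.1%, exact Fisher adjusted p = 0.540), as among the widest 50% of peaks (8.51% against 9.03%). Prf1, which encodes perforin, had peaks of 693 bp at the promoter and 511 bp at 37031 bp downstream, within intron 18 of another gene, Pald1. Gzmb, which encodes the protease granzyme B, had 1 peak of 503 bp at the promoter (chromosome 14, 56262217 to 56262719) and 4 peaks of 113 to 320 bp between 25572 and 34683 bp upstream. Other effectors with a peak were the death ligand gene Tnfsf10 (513 bp), Il12rb1 (418 bp) and Srgn (376 bp). No peak was assigned to Ifng, which encodes interferon-gamma, or to Tbx21, which encodes T-bet. Identity genes with the widest peaks were Cd244a (1061 bp), Id2 (665 bp, centred 3614 bp upstream of the TSS), Nfil3 (647 bp), Runx3 (432 bp) and Itgb2 (371 bp). The effector excess did not pass with a window of 1000 bp (26.7% against 15.1% of other genes, exact Fisher adjusted p = 0.169), with the widest 50% of peaks (16.7% against 9.02%, adjusted p = 0.306) or with either gene end (30% against 21.5%, adjusted p = 0.307), and among the widest 10% the share was 0% against 1.93%. The effector and identity shares did not differ by the exact Fisher test (adjusted p = 0.120), but did among segments of at least 200 bp (difference 25.1 percentage points, adjusted p = 0.0164).

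In IL-15 and JAK-STAT signalling, 11 of 41 genes had a peak (26.8%, 95% interval 14.2 to 42.9), which did not pass the exact Fisher test (adjusted p = 0.114). Peaks were found at Il2rb, the shared receptor chain of IL-2 and IL-15 (853 bp at the promoter and 1309 bp at 15548 bp upstream by the authors' distance, inside the gene as RefSeq draws it), the signalling inhibitors Socs1 (734 bp) and Socs3 (379 bp), Ptpn2 (532 bp) and Stat3 (412 bp). Markers of other cells rarely had peaks. None of 20 B and plasma cell genes had a peak (0 of 20, 95% interval up to 16.8%; exact Fisher adjusted p = 0.0910), nor did 25 liver genes or 25 neuron genes (0 of 25 in each, up to 13.7%; adjusted p = 0.0405 for each). Of 20 T cell genes, Lck (415 bp) and Cd3d (217 bp) had one (10%, exact Fisher adjusted p = 0.759), of 20 myeloid genes Cd68 (373 bp), and of 20 erythroid genes Tfrc (257 bp; 5% and adjusted p = 0.396 for both lists). The liver and neuron depletion did not pass among the widest 50% of peaks (exact Fisher adjusted p = 0.293), the widest 10% (adjusted p = 1) or segments of at least 200 bp (adjusted p = 0.0683). The 2 NK lists together had a higher share than the 4 blood cell lists together (22 of 77, 28.6%, against 4 of 80, 5%; exact Fisher adjusted p = 1.04e-04).

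Lists of constitutive genes set a level for genes that are expressed in most cells. Ribosomal protein genes had a peak in 28 of 45 cases (62.2%, 95% interval 46.5 to 76.2; exact Fisher adjusted p = 1.23e-11), among them Rpl10 (1995 bp), Rpl37 (1177 bp) and Rpl4 (1009 bp). Oxidative phosphorylation genes did in 8 of 39 (20.5%, 9.30 to 36.5; exact Fisher adjusted p = 0.409), among them Cycs, Atp5b (650 bp), Ndufb5 (517 bp), Sdhb (387 bp) and Uqcrb (354 bp). Counted at either gene end, the latter share was 43.6% and passed (exact Fisher adjusted p = 0.00509). The ER and secretory share of 86.3% exceeded the ribosomal share (exact Fisher adjusted p = 0.00119), the oxidative phosphorylation share (adjusted p = 7.73e-14) and the NK share given above. Peaks at ER and secretory genes were 632.5 bp wider in the median than at ribosomal protein genes (499.5 bp; permutation p = 2.00e-05).

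Among the 12 widest peaks within 5000 bp of a TSS, 4 were assigned to genes of the ER lists, Sec11c, Canx, Hspa5 and Pdia4, and 2 to Xbp1 and Creb3l2 of the list of sensors and factors. The others were assigned to Ppp1r10 (3413 bp, chromosome 17, 35915749 to 35919161, which also covers an end of Mrps18b), Trabd (3097 bp), Eif2a (2751 bp, with an end of the ER gene Serp1 inside), Gm6793 (2508 bp, over the start of the RefSeq gene Hnrnpa3), Ttc41 (2446 bp, with an end of the ER gene Hsp90b1 inside) and Eif1a (2430 bp, which also covers an end of the p24 transport gene Tmed7). The 5 widest peaks farther away were nearest to Gm5535 (1774 bp), 4930578M01Rik (1453 bp), Mir7683 (1310 bp), Il2rb (1309 bp) and 5031425F14Rik (1294 bp). Peaks within 1000 bp of a TSS were wider than the others, with medians of 403 bp (3639 peaks) and 310 bp (1251 peaks), a difference of 93 bp (permutation p = 1e-05, the smallest possible).

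Peaks were unevenly spread over the chromosomes. Chromosome 11 held 469 peaks, 2.13 times the number expected from its span (exact binomial adjusted p = 6.25e-50), and chromosome X held 72, 0.233 times the number expected (adjusted p = 1.58e-60). In all, 14 of 21 chromosomes departed from the expectation, 6 above and 8 below. With the number of protein-coding genes as the expectation, 6 departed, 2 above and 4 below, with chromosome 11 at 1.31 times (exact binomial adjusted p = 5.73e-08) and chromosome X at 0.334 times (adjusted p = 2.61e-29). Chromosome 7 turned from above the expectation by span (1.49 times, exact binomial adjusted p = 8.93e-14) to below that by gene number (0.865 times, adjusted p = 0.0117). No peak lay on chromosome Y or the mitochondrial genome, and 2 lay on unplaced contigs.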

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

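The detailed annotation column, which no comparison above uses, names a repeat element for 122 of the 4890 peaks (2.49%). It was picked out because it holds a signal in data that were not otherwise reported on, above the 3 peaks that a count of 0 would allow. Long terminal repeats had the most peaks, 51, of which 10 lay within 5000 bp of a TSS, and their median width was 300 bp. SINE elements had 28 peaks and LINE elements 26. The share of the genome in each class was not used here, so neither an excess nor a deficit was tested. The same column gives 457 other peaks the label CpG, and these were not compared with any background.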

How the results depend on the processing

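The comparisons between lists, the widths per list and the distal comparisons, and the alternatives with segments of at least 200 bp, either gene end, a curated background or gene number, were chosen after the data were seen. Of 255 values recomputed under alternatives, 236 kept their side of the threshold or, for counts, stayed within 1.5 times the main count. These include all 32 values of the 4 ER and secretory lists. Among the 236, values that passed in the main setting also kept their direction. Some that had not passed changed direction, such as effector minus identity genes, at -2.13 percentage points among the widest 10% of peaks. The number of lists that passed was 11 and ranged from 8 to 12 in the other settings, but was 6 with the widest 10% of peaks, where fewer genes have a peak. In that setting the NK effector share, 0%, lay below the 1.93% of other genes without passing, and the NK lists exceeded the other blood cell lists by 1.30 percentage points (exact Fisher adjusted p = 0.589). Among segments of at least 200 bp, effector exceeded identity genes by 25.1 percentage points and passed. The effector share stayed at 40%, and the identity share fell from 21.3% to 14.9%. The identity genes Prdm1 (112 bp), Runx1 (160 bp) and Klrd1 (190 bp) had no wider segment near the TSS and were lost to the cut. The identity list passed only when peaks at any distance counted (34.0%, exact Fisher adjusted p = 0.0119). Chromosomes departing from expectation numbered 14, against 9 with the widest 50% of peaks, where fewer peaks were tested, and 6 by gene number, where the expectation itself differs. No paired analysis was possible because the list combines the libraries. Leaving out each replicate, the agreement and reciprocal overlap of replicates, the motif search and its controls, the CpG-rich background and another strength column were not run. Library depth is unknown, so it sets an unknown limit on genes with no peak.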

Other observations

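The families, the distal comparison, the synthetase comparison and all patterns described here were chosen after the list shares had been seen. The bound of each test was set before its value was known, except for a requirement on chromosome X given there and the split of the synthetase genes. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were among the most often marked families. Of 20 cytosolic synthetase genes 16 had a peak within 5000 bp (80%, 95% interval 56.3 to 94.3), the widest at Vars (1066 bp), Eprs (1033 bp) and Mars1 (1033 bp). Cars, Farsb, Sars and Wars had none. Of 17 mitochondrial synthetase genes 8 had one (47.1%, 23.0 to 72.2), with an unadjusted exact Fisher p of 0.0470. The comparison was prompted by a family of 12 of these cytosolic genes that all had a peak, and in the other 8 the share was 50% (4 genes; exact Fisher p = 1 against the mitochondrial genes), so a difference between cytosolic and mitochondrial synthetases rests on the genes that prompted it and stays open. Sterol synthesis genes had a peak in 13 of 23 cases (56.5%; exact Fisher adjusted p = 1.94e-05 over 12 families), led by Insig1 (1112 bp), which restrains sterol synthesis. Translation initiation genes had one in 23 of 55 (41.8%, exact Fisher adjusted p = 1.09e-05) and proteasome genes in 21 of 48 (43.8%, adjusted p = 1.09e-05), where Psmb8 and Psmb10 of the immunoproteasome had the widest (1415 and 1049 bp). Olfactory receptor genes had 1 in 1106.

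A hypothesis was that the ER and Golgi theme extends to families outside the fixed lists. Only 2 of 5 such families passed the exact Fisher test, against a bound of 3 set beforehand. They were N-glycan assembly (13 of 19, 68.4%, exact Fisher adjusted p = 1.73e-06), with Alg8 at 1078 bp and Gmppa at 1009 bp, and the COG and TRAPP tethers (9 of 22, 40.9%, adjusted p = 0.00596). The share was 18.5% for GPI anchor synthesis (exact Fisher adjusted p = 0.662), 33.3% for the ER membrane and GET complexes (adjusted p = 0.0917) and 15.4% for the V-ATPase (adjusted p = 1).

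The first pattern weighed is the presence of peaks at 86.3% of ER and secretory genes. If promoters in constant use were marked alike, proteasome and mitochondrial ribosomal protein genes would reach that level, but 38.1% of them had a peak (48 of 126, exact Fisher p = 5.82e-16). Gene length does not account for the ER and secretory share, since the highest share in 10000 draws of genes matched on length was 32.1%. The proteasome and mitochondrial ribosomal protein families lie above the 15.9% of all genes, and ribosomal protein genes at 62.2%. Part of the list may therefore reflect promoters that precipitate with many antibodies. The IgG control that the protocol names, and the expression of these genes, were not analysed here, so this stays open.

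The second pattern is that genes of the NK lists were often nearest to peaks more than 5000 bp from a TSS: 16 of 77 (20.8%, 95% interval 12.4 to 31.5), against 6 of 131 ER and secretory genes (4.58%, exact Fisher adjusted p = 6.71e-04). It was not particular to NK genes: of the other lists, the sensors and factors (25%), ER import (13.5%) and IL-15 and JAK-STAT (12.2%) also exceeded the other genes by the exact Fisher test (adjusted p = 0.0150, 0.0150 and 0.0153). The space around genes does not account for it: the highest share in 10000 draws matched on the distance between neighbouring genes was 13.0%. Blood cell loci in general do not either, as 2.50% of B, T, myeloid and erythroid genes had one (2 of 80, exact Fisher p = 2.91e-04). As a hypothesis, these peaks may lie at regulatory elements in use in NK cells, whether XBP1s binds them directly or not; motifs were not searched, and a nearest gene need not be the target.

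The third pattern is the small number of peaks on chromosome X. If gene content were the cause, constitutive genes on X would have peaks as often as those on autosomes, and 4 of 7 did (57.1%, 95% interval 18.4 to 90.1), against 57% of 400 on autosomes. This met the bound set beforehand, but with 7 genes the interval is wide, and a requirement that the interval meet the bound too was added after the value was seen, so gene content and a chromosome-wide effect cannot be told apart. Signal along X could not be compared directly. Promoter peaks on X differed by -44 bp in the median from those on autosomes (359 against 403 bp, 61 and 3576 peaks; permutation p = 0.262), and since width is not a measure of signal this decides neither way.

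Runx3, which encodes a lymphocyte transcription factor, had 4 peaks more than 5000 bp away, from -50649 to 53780 bp from the TSS. Dad1, an oligosaccharyltransferase subunit, was nearest to 7 peaks, 6 of them between 20323 and 115230 bp downstream. Of these 6, the 3 farthest, of 33 to 463 bp, lie within the T cell receptor genes Tcra and Tcrd of the RefSeq table.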
